A study of Mus musculus with 12 samples.

How the data were processed

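Nuclei of adult mouse cardiomyocytes were taken from tamoxifen-treated Myh6-MCM mice (control) and from tamoxifen-treated mice that also carried the Yap5SA transgene (YAP5SA). Myh6-MCM drives a tamoxifen-inducible Cre recombinase from the promoter of the cardiac myosin gene Myh6. Per the labels' protocols, nuclei bound to beads through PCM1, a centriolar satellite protein used to select cardiomyocyte nuclei, gave the RNA, and libraries were made with a stranded kit with removal of ribosomal RNA and read from both ends. There were 4 nuclear RNA-seq libraries, replicates 1 and 2 of each group. The ATAC-seq and 4C-seq samples of the series were not analysed here.

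The deposited table held raw counts per gene symbol, not normalized, for the 4 libraries, in whole numbers. Reads had been mapped to the mouse genome mm10 with STAR, per the labels' protocols, and the submitters' processing notes name DESeq2 for the authors' own test. The counting program, its strand setting, the gene annotation and the tool versions are not given in the sources used here. This limits some genes. Without a stated strand setting, reads of a gene and of an overlapping gene on the other strand cannot be told apart, which among the genes checked and reported here concerns Myh1, Myh2, Myh6, Myh7, Myl4, Ckm, Col4a1, Col4a3, Ctgf, Irf7, Ezr, Dusp1, Hspa1a, Atcay, Chd5, Krt7, Tgfb3, Vcam1, Actn1, Hopx, Yap1, Shmt2, Malat1 and Xist. Overlaps were checked between exons only, so genes that overlap another within introns may be missing from these. Near-identical copies can also share reads, which makes Hspa1a and Hspa1b, Bglap3 and its neighbouring copies, and the Myh genes uncertain. Whether reads of the Yap5SA transgene were counted under Yap1 is not given in the sources used here. Counting in nuclear RNA includes unspliced transcripts only where the counting took intronic reads, which is not stated either.

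The table had 46983 gene symbols, of which 30546 had a count in any library. Coordinates and gene types were taken from GENCODE M21 (GRCm38, the assembly called mm10): 44046 symbols matched directly, 777 through an older symbol, 99 are shared by several genes (Aldoa among them) and 2061 did not match. Total counts were 10927396 and 7850661 in control replicates 1 and 2, and 15012122 and 12806949 in YAP5SA replicates 1 and 2. A count of 0 allows up to 3 counts, which is 0.272 and 0.397 CPM (counts scaled to a common library total) in the control libraries and 0.202 and 0.228 CPM in the YAP5SA libraries. Such floors and all counting intervals cover counting error only, since reads carried no molecular identifiers.

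The tests were chosen before the data were examined. Genes were kept by the edgeR function filterByExpr (minimum count 10), which left 17715 genes, and libraries were scaled by TMM. The quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) compared the 2 YAP5SA with the 2 control libraries without a replicate block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Adjusted p-values of single genes come from this test unless another is named. Log2 fold changes are YAP5SA minus control, with the standard error (SE) taken as the size of the fold change divided by the square root of F. CPM values use the TMM-scaled totals and are given as mean ± SD. A fold against a group at 0 was computed against the floor of 3 counts per library, and with 1 to 3 counts in a group the ratio of summed counts is given with its exact 95% binomial counting interval. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

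Before the data were examined, 33 gene lists were fixed: pathways, markers of other heart cell types, and signs of RNA quality. Circadian clock and sex-linked genes were placed with the last, although they do not measure RNA quality. Of these, 31 had at least 3 tested genes and entered one family (sex-linked genes were kept out, and 1 lymphocyte gene was tested). The list test was camera with a preset inter-gene correlation of 0.01, two-sided, against all tested genes, adjusted over the 31 lists. Beside it stand camera with an estimated correlation, fry, and the number of members past the threshold over all genes and adjusted over the list alone. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries, and with the preset one from the tested genes. With so few libraries this alone raises p. The rule for named genes took Yap1, its paralog Wwtr1, and Wls and Nog, the 4C-seq viewpoint genes. It added the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups' libraries, leaving out symbols that are only model names. From each list it took up to 4 examples, the 2 smallest adjusted p in each direction. Other genes named were chosen after their values were seen.

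The pipeline was tested on simulated data for the same comparison, with counts drawn from the means and totals of these libraries over 17317 tested genes in 5 simulations. It recovered 19.2% of genes changed 2-fold, 81.7% of those changed 4-fold and 98.2% of those changed 8-fold, with 2.84% of calls false. Both groups were given the same spread between replicates, taken from the fitted trend, while the real control pair varied more than the YAP5SA pair. These rates may therefore not hold for the real libraries. A shifted list was called in 5 of 5 simulations and an unshifted list in 0 of 5, at an unadjusted p under 0.05. This held for camera with the preset correlation and for camera with an estimated one. Genes were drawn independently, so these list results do not cover correlated genes. In the real lists the estimated correlation ran from -0.0968 (smooth muscle and pericyte markers) to 0.982 (mitochondrially encoded genes), with 0.87 for adult sarcomere genes.

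Alternatives fixed in advance were DESeq2 1.42.0 (Wald test), limma-voom (limma 3.58.1), the size factors of DESeq2, library totals alone, no filter, a filter of at least 1 CPM in at least 3 libraries, leaving out mitochondrial, Malat1, Neat1 and ribosomal RNA genes, a replicate block, stricter thresholds, and leaving out each library in turn. A fit that also leaves out Gm26917 and Rn7sk, and limma-voom with sample quality weights, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.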

Results

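Nuclear RNA of adult mouse cardiomyocytes was sequenced to ask how YAP5SA, a form of the transcriptional co-activator YAP whose inhibitory serines are replaced by alanine, changes transcript levels in the heart muscle cell. There were 2 control libraries and 2 YAP5SA libraries, with total counts from 7850661 to 15012122. No replicate pair agreed within sampling noise (chi-square per gene of 61.9 for the control pair and 15.2 for the YAP5SA pair), so none was counted as a duplicate. The control libraries differed more from each other than the YAP5SA libraries did. The biological coefficient of variation was 34.3% in the control pair and 8.44% in the YAP5SA pair, and Pearson's r across genes, which are not independent replicates, was 0.941 and 0.990. The first principal component held 63.8% of the variance and separated the groups, and the second held 30.7% and separated the control libraries.

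Of the genes the design singles out, Nog, which encodes the BMP antagonist noggin (chromosome 11, 89300638 to 89302332, mm10), rose from 0.836 ± 0.995 CPM in control to 53.8 ± 0.4003 CPM in YAP5SA (SD, n = 2), a log2 fold change of 5.84 (SE 0.612, adjusted p = 0.0250). The control level rests on 17 counts in replicate 1 and 1 count in replicate 2. Without control replicate 1 the log2 fold change of Nog was 8.57. Wls, which encodes the carrier needed for secretion of Wnt proteins (chromosome 3, 159839672 to 159938664), measured 166 ± 33.4 CPM in control and 361 ± 16.3 CPM in YAP5SA (SD, n = 2), a log2 fold change of 1.12 (SE 0.215). Its adjusted p of 0.0545 missed the threshold, which it passed with DESeq2 (adjusted p = 0.000809) and with scaling by library totals (adjusted p = 0.0456). Over all alternatives the adjusted p of Wls ran from 5.37e-16 without control replicate 2 to 0.533 without YAP5SA replicate 2. Yap1 (chromosome 9, 7931999 to 8004596) measured 152 ± 19.7 CPM in control and 164 ± 4.61 CPM in YAP5SA, and its paralog Wwtr1, which encodes TAZ, 142 ± 16.6 and 120 ± 6.02 CPM (SD, n = 2). Neither passed (adjusted p = 0.750 and 0.455). Since transgene reads may not have been counted under Yap1, its level checks nothing about the labels.

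Across 17715 tested genes, 553 rose and 177 fell in YAP5SA, so that 75.8% of the calls were increases, and 4190 genes had an unadjusted p under 0.05. Of the increases, 533 were at least 2-fold, as were 172 of the decreases, and 677 of the 730 called genes are protein coding. Leaving out single libraries moved these counts widely. Without control replicate 1 there were 3496 higher and 3223 lower genes, and without control replicate 2 there were 3749 and 3554. Without YAP5SA replicate 1 the counts were 68 and 5, and without YAP5SA replicate 2 they were 27 and 0, with 1514 genes at an unadjusted p under 0.05 in that last fit. In each such fit the lone library of its group was assumed to vary like the pair of the other group. DESeq2, run on 30546 genes without the edgeR filter, called 1069 and 527 genes, and an edgeR fit with no filter on low counts 1727 and 1689.

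Most of the 10 largest increases named by the rule were from a few counts or none in control. Cemip, which encodes a protein that takes part in hyaluronan breakdown (chromosome 7, 83932857 to 84086502), rose from 6.46 ± 0.346 to 1103 ± 29.5 CPM (SD, n = 2), a 170-fold increase (adjusted p = 0.00425). Tnfsf15, a cytokine gene of the tumor necrosis factor family, rose 252-fold from 2 counts in each control library, and Frmpd1 rose 141-fold, also from 2 counts in each. Lrtm2 rose 68.5-fold and Igfbp2, which encodes an insulin-like growth factor binding protein, 63.7-fold. The summed counts of Vnn1, which encodes a pantetheinase, were 177 times higher (95% counting interval 48.7 to 1460), those of Tmem130 154 times (52.4 to 747) and those of Il23r, a subunit of the interleukin-23 receptor, 84.4 times (28.7 to 411). A pair of skeletal myosin heavy chain genes lie beside each other on chromosome 11 and are among these genes. Myh2 (67171027 to 67197517) had 0 counts in both control libraries and 143 and 251 in the YAP5SA libraries, at least 42.9-fold higher, and Myh1 (67200052 to 67224575) went from 1 and 0 counts to 180 and 226, a ratio of 270 (counting interval 48.1 to 10700). Adjusted p of these 10 genes ran from 0.00425 to 0.0289. The call of Myh2 was lost without YAP5SA replicate 2, as was that of Igfbp2, and the calls of the other 8 held when either YAP5SA library was left out.

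The largest decreases were led by muscle and secreted protein genes. Acta1, the skeletal alpha-actin gene (chromosome 8, 123891769 to 123894751), fell from 670 ± 93.6 to 48.1 ± 5.07 CPM (SD, n = 2), a log2 fold change of -3.80 (SE 0.235, adjusted p = 0.00930). The log2 fold change was -4.77 for Tnnt3, which encodes fast skeletal troponin T, and -3.45 for Myot, which encodes the Z-disc protein myotilin. It was -5.27 for Bglap3, a gene of the osteocalcin family, -3.66 for Agt, which encodes angiotensinogen, -3.62 for Gpnmb, and -3.56 for Hspa1a, which encodes an inducible HSP70 chaperone. For Slc4a8, a bicarbonate transporter gene, it was -3.32, for Chd5, a chromatin remodeler gene, -3.17, and for Atcay -3.06. Adjusted p of these 10 genes ran from 0.00930 to 0.0465. Control replicates differed for several of them, as with 44.0 and 13.8 CPM of Bglap3 and 73.3 and 26.6 CPM of Gpnmb. The calls of Agt, Bglap3, Chd5, Gpnmb, Myot, Slc4a8 and Tnnt3 were lost with limma-voom, that of Chd5 also with the stricter filter, and none of the 10 kept its call without YAP5SA replicate 2.

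**Figure D1:**
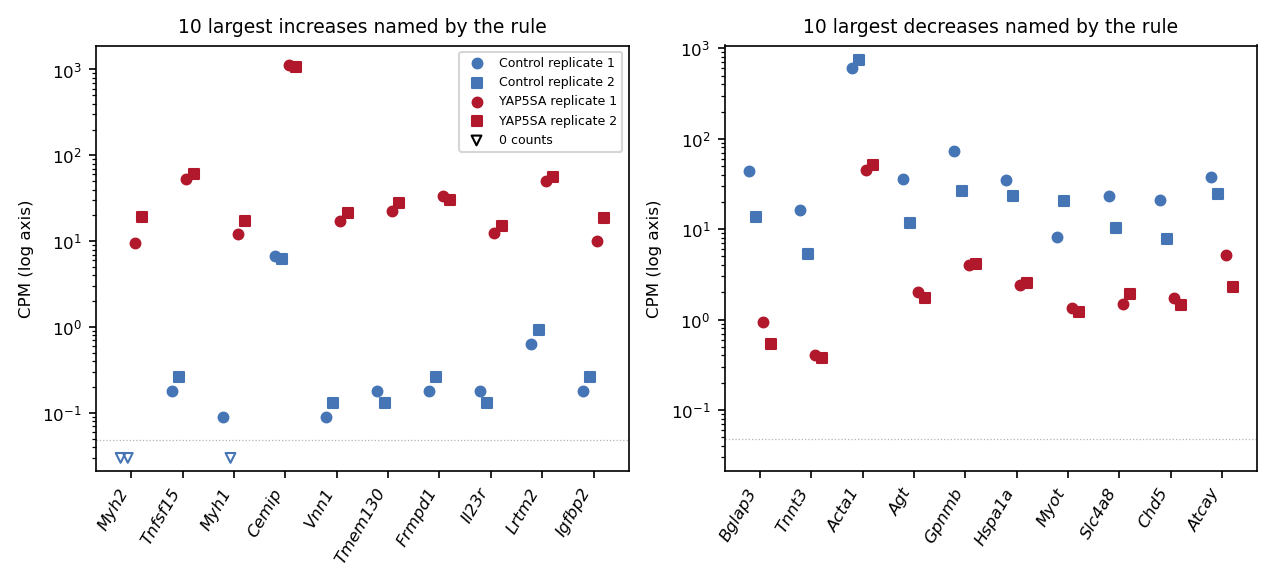
CPM (log axis) of the 10 largest increases (left) and the 10 largest decreases (right) named by the rule, with 1 point per library and control libraries in blue, YAP5SA libraries in red; libraries with 0 counts are drawn as open triangles under the dotted line. Cemip stood at 6.70 and 6.21 CPM in the control libraries and at 1124 and 1082 CPM in the YAP5SA libraries.

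Genes of the Hippo pathway, which restrains YAP, and known YAP-TEAD targets moved upward as lists. Of 30 tested Hippo pathway components, 8 rose and 0 fell (14 and 1 adjusted over the list alone), with a median log2 fold change of 0.42 and a camera adjusted p of 5.32e-09 (adjusted p = 0.385 with an estimated correlation). Wwc1, which encodes the upstream Hippo activator KIBRA, rose from 1.34 ± 0.405 to 49.6 ± 0.2998 CPM (SD, n = 2; log2 fold change 5.16, SE 0.262, adjusted p = 0.00638). Vgll3, which encodes a TEAD cofactor, rose 3.52-fold. The other members that rose were Lats2 and Stk4, which encode kinases of the pathway, Tead4, Vgll4, Ajuba and Amotl2. Of 21 tested genes of the YAP-TEAD target signature, 7 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.64, camera adjusted p = 8.70e-07; adjusted p = 0.385 with an estimated correlation), Amotl2 3.92-fold and Dock5 3.11-fold. Amotl2, Lats2 and Ptpn14 stand in both lists. Well-known targets whose control replicates differed did not pass: Ctgf was at 420 and 2789 CPM in the control libraries and 1236 and 1535 CPM in the YAP5SA libraries (log2 fold change -0.21, SE 0.819, adjusted p = 0.904), Cyr61 at 238 and 1119 against 1599 and 1929 CPM, and Ankrd1 at 900 and 3241 against 3100 and 3362 CPM. Without control replicate 2 the log2 fold change of Ctgf was 1.76 and without control replicate 1 it was -1.001. With limma-voom it was 0.29. The test fry called the Hippo list (adjusted p = 0.0316) and missed for the target signature (adjusted p = 0.0502). When either YAP5SA library was left out, 0 members of the target list and 1 of the Hippo list (Wwc1) passed. Without control replicate 1, 14 target genes rose and 1 fell, and 18 Hippo genes rose and 1 fell. Without control replicate 2, 14 target genes rose and 2 fell, with a median of 0.99, and 16 Hippo genes rose and 3 fell.

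The actin cytoskeleton and adhesion list was also higher, with 5 of 31 tested members past the threshold upward and 0 downward (11 and 3 adjusted over the list alone; median 0.47, camera adjusted p = 0.000152, adjusted p = 0.512 with an estimated correlation). Ezr, which encodes the membrane-to-actin linker ezrin, rose from 38.7 ± 4.51 to 216 ± 15.6 CPM (SD, n = 2; adjusted p = 0.0129), and Actn1, which encodes non-muscle alpha-actinin, rose 3.44-fold (adjusted p = 0.0278). Cnn2, Cald1 and Cdc42ep3 also rose. The number that rose was 1 without YAP5SA replicate 1 and 0 without YAP5SA replicate 2, while 16 rose and 6 fell without control replicate 1, and 17 rose and 5 fell without control replicate 2.

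Cell cycle genes were higher in both phases tested. Of 25 tested G2/M and cytokinesis genes, 9 rose and 0 fell (24 and 0 adjusted over the list alone), and all 25 had a positive fold change, with a median of 1.22 and a camera adjusted p of 6.74e-17 (adjusted p = 0.542 with an estimated correlation). Anln, which encodes the contractile ring protein anillin, rose 3.14-fold (adjusted p = 0.0314) and Ect2, which encodes an activator of RhoA in cytokinesis, 2.51-fold (adjusted p = 0.0356). Mki67, the gene of the proliferation marker Ki-67, was chosen after its values were seen. It measured 114 ± 20.9 CPM in control and 275 ± 54.6 CPM in YAP5SA (SD, n = 2) and missed the threshold (adjusted p = 0.0521). Of 26 tested G1/S and DNA replication genes, 8 rose and 0 fell (19 and 0 adjusted over the list alone; median 1.07, camera adjusted p = 4.41e-13; adjusted p = 0.512 with an estimated correlation), among them Mcm2 3.24-fold and Mcm5 2.97-fold, which encode parts of the replicative helicase. Of 16 cell cycle inhibitors 0 passed with edgeR and 1 fell with DESeq2, and 4 higher and 1 lower members had an unadjusted p under 0.05 (median 0.02, mean -0.02, camera adjusted p = 0.936). Markers of macrophages, a cell type that can divide, were higher in the same libraries, with a median log2 fold change of 1.48. In either cell cycle list, 0 members passed without YAP5SA replicate 1 or without YAP5SA replicate 2, while at least 21 passed when either control library was left out.

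Markers of macrophages and monocytes and interferon-induced genes were higher in YAP5SA. Of 13 macrophage and monocyte markers, 6 rose and 0 fell (12 and 0 adjusted over the list alone), and 13 had a positive fold change (camera adjusted p = 7.49e-13; adjusted p = 0.385 with an estimated correlation). Fcgr1, an Fc receptor gene, rose from 6.94 ± 0.466 to 25.6 ± 1.88 CPM and Cd14, which encodes a lipopolysaccharide co-receptor, from 16.5 ± 3.01 to 53.4 ± 2.29 CPM (SD, n = 2; adjusted p = 0.0266 and 0.0284). Of 15 interferon response genes, 7 rose and 0 fell (15 and 0 adjusted over the list alone; median 1.48, camera adjusted p = 7.49e-13; adjusted p = 0.512 with an estimated correlation), Ifit1 3.54-fold and Irf7, which encodes a transcription factor of the interferon response, 2.90-fold. Lists of other cell types moved in both directions. The 12 endothelial markers had a median of -0.79, with Vwf and Robo4 past the threshold downward (7 adjusted over the list alone; camera adjusted p = 0.000120; adjusted p = 0.604 with an estimated correlation), and the 8 smooth muscle and pericyte markers a median of -0.86 with 0 members past it, 5 lower at an unadjusted p under 0.05 and 2 adjusted over the list alone or with DESeq2 (camera adjusted p = 0.0132; adjusted p = 0.512 with an estimated correlation). Of 12 fibroblast markers, Lum rose 2.24-fold, and that list was not called (2 rose adjusted over the list alone; median -0.33 against a mean of 0.06 and an upward test, camera adjusted p = 0.565). Epicardial (median 0.83), Schwann cell (median -0.97) and erythroid lists (median -0.39) were not called (camera adjusted p = 0.0728, 0.157 and 0.442), and 0 of their members passed with edgeR. Adjusted over the list alone, 4 epicardial genes rose and 2 fell, the same numbers as at an unadjusted p under 0.05, and 3 rose with DESeq2, while 1 Schwann cell and 0 erythroid genes had an unadjusted p under 0.05. The epicardial list was called with no filter, without control replicate 1 and without YAP5SA replicate 1, and the erythroid list without control replicate 1. The 1 lymphocyte marker tested, Cd79a, measured 7.16 and 1.06 CPM in the control libraries and 0.404 and 0.684 CPM in the YAP5SA libraries (adjusted p = 0.148). Robo4 lost the call with the stricter filter. The macrophage, interferon and endothelial counts were 0 when either YAP5SA library was left out. They were 13, 14 and 8 without control replicate 1, with an endothelial median of -0.46 and a smooth muscle median of -0.55, and 12, 15 and 12 without control replicate 2, and the camera calls of these 3 lists held in all 4 fits that left out a library. Of the smooth muscle genes 5 fell and 0 rose without control replicate 1, and 5 fell and 1 rose without control replicate 2.

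Genes of the contractile apparatus and of oxidative metabolism were lower as lists, with few members past the threshold on their own. Of 24 adult sarcomere genes, 23 had a negative fold change (median -1.01, camera adjusted p = 1.31e-06; adjusted p = 0.642 with an estimated correlation), and Tcap, which encodes the Z-disc protein telethonin, fell from 85.6 ± 19.5 to 29.2 ± 0.143 CPM (SD, n = 2; adjusted p = 0.0321). Adjusted over the list alone, 7 fell. Of 24 calcium handling and ion channel genes, Hrc, which encodes a calcium-binding protein of the sarcoplasmic reticulum, fell 2.51-fold and Kcnj5, a potassium channel gene, 2.17-fold (2 adjusted over the list alone; median -0.49, camera adjusted p = 0.00360; adjusted p = 0.681 with an estimated correlation). Of 26 fatty acid oxidation genes, Hadh, which encodes an enzyme of beta-oxidation, fell 2.14-fold (2 adjusted over the list alone; median -0.59, camera adjusted p = 0.000152; adjusted p = 0.512 with an estimated correlation). Of 26 respiratory chain and TCA cycle genes 0 passed, also when adjusted over the list alone, 1 fell with DESeq2 and 10 lower genes had an unadjusted p under 0.05 (median -0.40, camera adjusted p = 0.000527; adjusted p = 0.642 with an estimated correlation), while 24 had a negative fold change. Control replicate 1 lay below control replicate 2 by a median of 0.86 on the log2 scale over the sarcomere genes and by 1.13 over the calcium handling genes. Without control replicate 2 the sarcomere median was -0.27 (camera adjusted p = 0.0169, the largest over the alternatives, which began at 2.86e-32) and the calcium handling call was lost (median 0.0082, camera adjusted p = 0.665; range over the alternatives from 5.38e-14). In that fit 8 sarcomere genes fell and 2 rose, and 6 calcium handling genes fell and 9 rose, while without control replicate 1 the numbers that fell were 22 and 22. The respiratory chain call was lost without YAP5SA replicate 1 (camera adjusted p = 0.0699; range from 6.12e-06). When either YAP5SA library was left out, 0 members of these 4 lists passed, and the calls of Tcap, Hrc, Kcnj5 and Hadh were lost. Kcnj5 and Hadh also lost the call with the stricter filter, and Hadh with library totals alone, so that 0 fatty acid oxidation genes passed in either setting. In the fatty acid oxidation list 15 fell and 1 rose without control replicate 1, and 17 fell and 1 rose without control replicate 2. In the respiratory chain list, in the same order, 17 fell and 0 rose, and 15 fell and 1 rose.

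**Figure D2:**
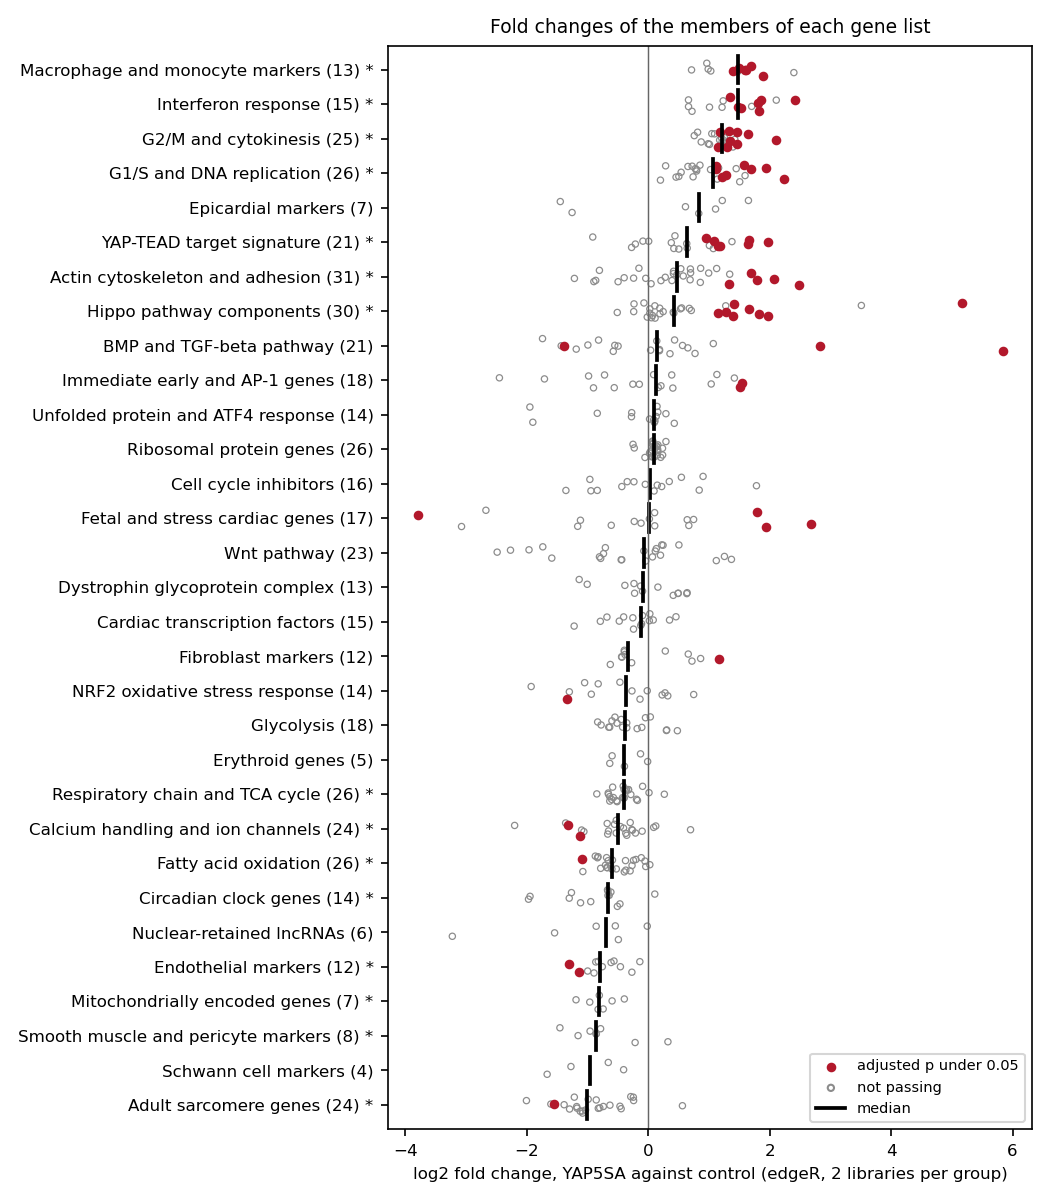
Log2 fold change (YAP5SA against control) of each tested member of the 31 gene lists, with filled points for genes past the edgeR threshold, open points for the others and a bar at the median; the number of tested genes stands in brackets and a star marks lists with a camera adjusted p under 0.05. Medians ran from -1.01 for adult sarcomere genes to 1.48 for the macrophage and interferon lists, and 15 lists carry a star.

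Lists fixed for developmental and stress programs moved in both directions or not at all. Among 17 fetal and stress cardiac genes 3 rose and 1 fell (3 and 2 adjusted over the list alone; median 0.02, camera adjusted p = 0.936). Actn1, Acta2 and Myl4, the atrial light chain gene, which rose 3.84-fold, stood against Acta1, and the list's mean was -0.24. The list's direction followed the control libraries, with a median of -0.23 and a downward call without control replicate 1 and a median of 0.52 without control replicate 2. Of 21 BMP and TGF-beta pathway genes, Nog and Tgfb3 rose, the latter from 37.0 ± 8.19 to 263 ± 45.0 CPM, and Id3, a target of BMP signaling, fell 2.61-fold (SD, n = 2; camera adjusted p = 0.366; 3 rose and 4 fell adjusted over the list alone). The list's median was 0.14, and -0.03 without control replicate 1, where the list was called. Of 18 immediate early genes Fos rose 2.91-fold and Dusp1, which encodes a phosphatase of MAP kinases, 2.87-fold (5 rose and 2 fell adjusted over the list alone; median 0.13, camera adjusted p = 0.266; called without control replicate 2). Nqo1, a target of the oxidative stress factor NRF2, fell 2.54-fold, the single call among 14 genes of that list (1 adjusted over the list alone; median -0.37, camera adjusted p = 0.0947; called without control replicate 2). The calls of Id3, Fos, Dusp1, Nqo1 and Myl4 were lost when either YAP5SA library was left out, and that of Tgfb3 without YAP5SA replicate 2. Id3 also lost the call with the stricter filter. Without control replicate 1, 3 fetal and stress genes rose and 7 fell, against 9 and 3 without control replicate 2. In the same order these numbers were 8 and 4 against 7 and 7 for BMP and TGF-beta genes, 7 and 5 against 9 and 3 for immediate early genes, and 4 and 3 against 1 and 10 for NRF2 genes. Of 23 Wnt pathway genes 0 passed with edgeR, 3 rose and 2 fell with DESeq2, and 3 higher and 5 lower genes had an unadjusted p under 0.05 (3 rose and 4 fell adjusted over the list alone; median -0.07, camera adjusted p = 0.376). No member passed among 18 glycolysis genes (camera adjusted p = 0.0967), 15 cardiac transcription factors (0.374), 13 genes of the dystrophin complex (0.936) and 14 genes of the unfolded protein and ATF4 response (0.976). Their medians were -0.39, -0.12, -0.09 and 0.10, against an upward test for the dystrophin complex and a mean of -0.27 and a downward test for the ATF4 list. At an unadjusted p under 0.05 there were 3, 2, 3 and 0 genes in these 4 lists, and DESeq2 called 1 higher and 1 lower gene of the dystrophin complex and 0 in the others. Adjusted over the list alone, 1 gene of the dystrophin complex fell and 0 of the others passed. Glycolysis was called downward with limma-voom, with quality weights, without control replicate 1 and without YAP5SA replicate 2. The dystrophin and ATF4 lists were called when either control library was left out, in opposite directions, with medians of -0.32 and 0.62 without control replicate 1 and 0.36 and -0.34 without control replicate 2. The smallest p in these 4 lists belonged to Aldoa, Hopx, Sgca and Shmt2, with log2 fold changes of -0.78, -0.79, -1.004 and 0.43.

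Measures of RNA quality differed between libraries, and circadian clock and sex-linked genes, which do not measure it, are given with them. The 7 tested mitochondrially encoded genes had a median log2 fold change of -0.81 (2 fell adjusted over the list alone and 0 over all genes, 3 lower at an unadjusted p under 0.05; camera adjusted p = 0.00666; adjusted p = 0.642 with an estimated correlation), and mitochondrial counts made up 0.370% and 0.223% of the control libraries and 0.166% and 0.173% of the YAP5SA libraries. The 14 circadian clock genes had a median of -0.67 (camera adjusted p = 0.00175; adjusted p = 0.604 with an estimated correlation) with 0 members past the edgeR threshold, 3 lower adjusted over the list alone or with DESeq2 and 6 lower at an unadjusted p under 0.05, Per3 having the smallest p (log2 fold change -1.11, adjusted p = 0.0742). Both calls were lost without control replicate 1 (medians -0.26 and -0.34; camera adjusted p = 0.0691 and 0.107, the largest over the alternatives, which began at 1.98e-07 and 3.51e-08). In that fit 3 mitochondrial genes fell, and 6 circadian genes fell and 1 rose, while without control replicate 2, 7 and 12 fell and 0 rose. Ribosomal protein genes (median 0.09) and nuclear-retained lncRNAs (median -0.70) were not called (camera adjusted p = 0.538 and 0.161), except without control replicate 1, and 0 and 1 of their members had an unadjusted p under 0.05, with 0 past the edgeR threshold. Gm26917, an RNA gene on chromosome 17, took 12.96% and 7.91% of the control counts and 12.5% and 7.93% of the YAP5SA counts. The Y-linked gene Ddx3y measured from 97.0 to 109 CPM in the 4 libraries and Xist from 4.26 to 18.8 CPM, and 0 of 5 sex-linked genes passed (1 at an unadjusted p under 0.05, 0 with DESeq2).

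**Figure D3:**
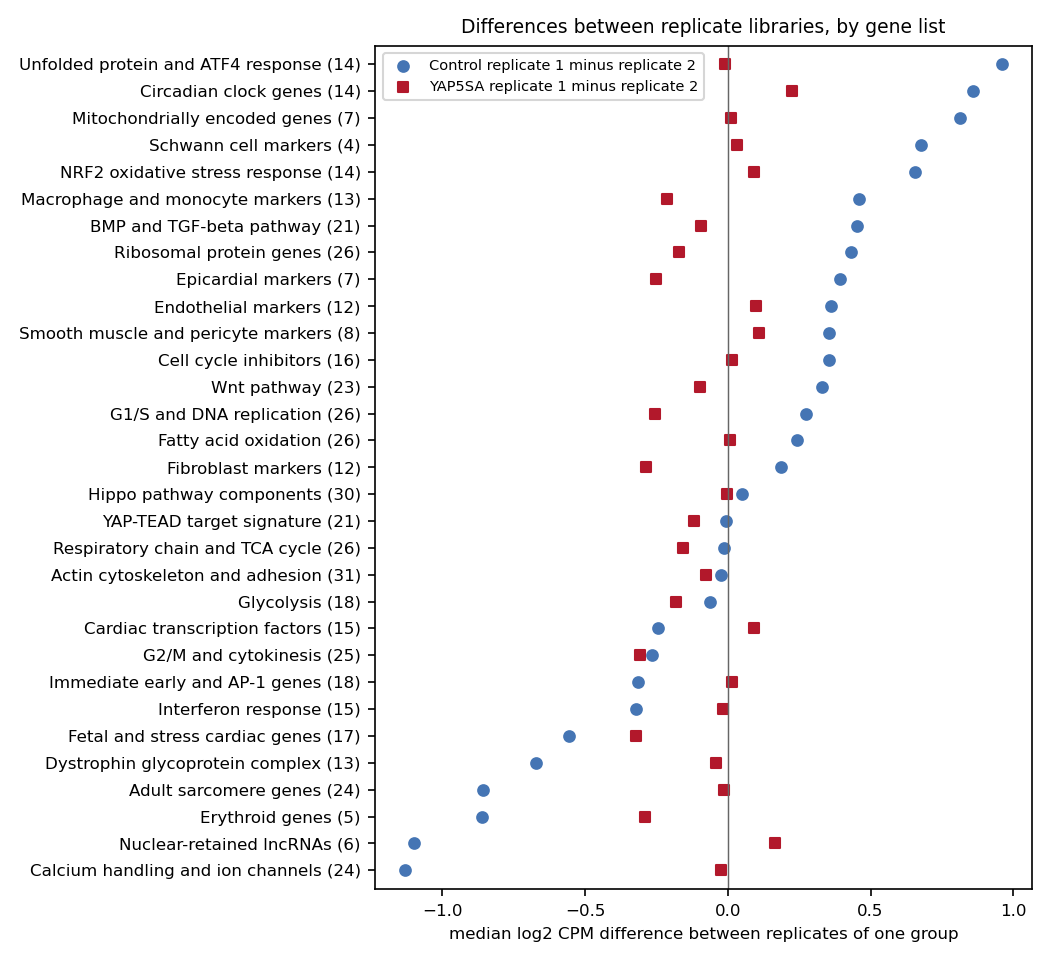
Median difference in log2 CPM between replicate 1 and replicate 2 over the tested genes of each of the 31 lists, for the control pair (circles) and the YAP5SA pair (squares), with the number of genes in brackets. The control pair ran from -1.13 for calcium handling genes to 0.96 for the unfolded protein and ATF4 list, and the YAP5SA pair from -0.32 for fetal and stress cardiac genes to 0.23 for circadian clock genes.

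In all, 15 of the 31 lists were called by camera with the preset correlation, 7 upward and 8 downward. With an estimated correlation 0 were called, the smallest adjusted p being 0.385, while 3 lists (Hippo components, YAP-TEAD targets and macrophage markers) had an unadjusted p under 0.05. For the Hippo and YAP-TEAD lists the estimates, -0.0154 and -0.00848, lay under the preset 0.01. Their unadjusted camera p still went from 8.57e-10 to 0.02 and from 1.68e-07 to 0.0291, so correlation does not account for the loss of these calls. By its directional test fry called 1 list. Its mixed test, which takes changes in either direction, called 15, among them fetal and stress cardiac genes (adjusted p = 0.00633). No list held a gene at 0 counts in a whole group.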

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

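The alternatives that leave out Gm26917 and Rn7sk and that weight libraries by quality were chosen after seeing the data. The counts of 553 higher and 177 lower genes stayed within 1.5 times under limma-voom, the size factors of DESeq2, library totals, the removal of abundant gene classes with or without Gm26917 and Rn7sk, and the 2-fold minimum. They moved to 1069 and 527 with DESeq2, which was run on 30546 genes without the edgeR filter. These calls held 553 and 176 of the same genes. The counts were 1727 and 1689 in edgeR with no filter, and 14 and 1 at an adjusted p under 0.01. The cause was not tested for DESeq2 and the missing filter, and the last follows from the stricter threshold. The stricter filter, which tested 16127 genes, gave 371 higher and 105 lower genes, and quality weights 700 and 464; the cause was not tested. Leaving out 1 library gave from 27 to 3749 higher and from 0 to 3554 lower genes, with fewer samples in each fit and, where 1 control was left, the spread taken from the YAP5SA pair alone. The replicate block gave 321 higher and 112 lower genes, of which 299 and 79 were among the calls without it, and left the number of lists called at 15. Of the genes named by the rule, Vwf, Robo4, Lum, Id3, Nqo1, Ect2, Hadh and Kcnj5 lost the call under the block. Over all genes same-numbered libraries did not deviate together (correlation of deviations -0.092), although the share of Gm26917 was close within each number (12.96% and 12.5%, 7.91% and 7.93%), and the labels state no pairing. Of the 15 lists called, 0 were called with an estimated correlation and 1 with fry; the other settings gave 14 to 22. Of the 48 called genes named by the rule, 18 kept the call without YAP5SA replicate 1 and 10 without YAP5SA replicate 2, and none changed sign in any fit. The median of the heat shock and chaperone list was 0.0869 with all libraries, where the list was called, and -0.131 without YAP5SA replicate 2. Where any other value was called in either fit, it changed sign only when a control library was left out. Values called in neither also changed sign in other fits, such as the log2 fold change of Ctgf (0.29 with limma-voom, 0.35 with the block) and the dystrophin median (0.0078 and 0.056). Over the 4 fits that left out 1 library, medians ran from -0.23 to 0.52 (fetal and stress genes), -0.87 to 0.0082 (calcium handling), -0.0295 to 0.175 (BMP and TGF-beta), -0.32 to 0.36 (dystrophin complex) and -0.34 to 0.62 (unfolded protein and ATF4), and log2 fold changes from -1.97 to 1.40 (Myh7), -2.29 to 0.90 (Fkbp5), -1.04 to 0.90 (Sgk1), -1.001 to 1.76 (Ctgf), -2.95 to 0.77 (Esr1) and -1.27 to 0.89 (Xist). Depth limits the genes near 0 in control, where 3 counts are 0.272 to 0.397 CPM.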

Other observations

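The tests on the mix of nuclei and on the skeletal myosins were chosen after their results had been seen. So were the comparison of G2/M and macrophage genes with each library left out, which returned the reading of the G2/M value to open after it had been taken as going with the explanation, and the sign test against the sarcomere median, added after a sign test against 0. The tests of gene length, of glucocorticoid-responsive genes and of the median of muscle-restricted metabolic genes were set before, although 2 of the 16 glucocorticoid genes and 5 of the 13 metabolic genes also stand in lists examined earlier. The 6 gene lists added here were chosen after some of their members or related genes had been seen, and their camera adjusted p-values are over these 6 lists.

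Genes of leukocyte attraction and adhesion were higher in YAP5SA: 6 of 22 tested cytokine, chemokine and adhesion receptor genes rose and 1 fell (median log2 fold change 1.27, camera adjusted p = 1.21e-09; adjusted p = 0.192 with an estimated correlation). The control libraries differed over this list, with a median of -0.736 for replicate 1 minus replicate 2 on the log2 scale (percentile 0 of 10000 random lists matched on expression). Without control replicate 1 the median was 1.15, with 10 genes that rose and 1 that fell, and without control replicate 2 it was 2.10, with 17 and 1. Without YAP5SA replicate 1, 3 rose and 0 fell, and without YAP5SA replicate 2 none passed, while the camera call held in all 4 fits. Csf1, which encodes the macrophage growth factor M-CSF, rose from 114 ± 21.9 to 1085 ± 156 CPM (SD, n = 2; adjusted p = 0.0166), Vcam1 rose 5.92-fold (adjusted p = 0.0157) and Ccl2, which encodes a monocyte chemokine, 3.59-fold (adjusted p = 0.0359), while Cxcl12 fell by 1.44 on the log2 scale (adjusted p = 0.0354). Macrophage and monocyte markers were higher in the same libraries as these genes (median 1.48), and RNA pooled over nuclei does not name the cell of origin. Among 19 basement membrane genes, 2 rose and 0 fell (median 0.27, camera adjusted p = 0.000113, and 0.185 with an estimated correlation). These were the neighbouring collagen IV genes Col4a3 and Col4a4, which are transcribed in opposite directions on chromosome 1 and rose 32.8-fold and 14.3-fold (adjusted p = 0.00638 and 0.00738). Col4a1, the gene of a widespread collagen IV chain, had a log2 fold change of -0.25 (adjusted p = 0.717). The simple epithelial keratin gene Krt7 rose 23.9-fold (adjusted p = 0.0112). The calls of Col4a3, Col4a4 and Krt7 held in all alternatives that gave a value, those of Csf1 and Vcam1 were lost without YAP5SA replicate 2 and that of Ccl2 when either YAP5SA library was left out. Of the basement membrane genes, 10 rose and 2 fell without control replicate 1, and 8 rose and 4 fell without control replicate 2.

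Among 16 heat shock and chaperone genes, 3 fell, Hspa1a 11.8-fold, Hspa1b 6.84-fold and Hspb1 4.03-fold (adjusted p = 0.0166, 0.0287 and 0.0278), and 0 rose. The list's camera test pointed down (adjusted p = 0.00256, and 0.315 with an estimated correlation) although its median was 0.09. The call was lost without YAP5SA replicate 1, where the median was 0.225. The median was -0.131 without YAP5SA replicate 2, 0.085 without control replicate 1 and 0.0153 without control replicate 2. Hspa1a lost its call without YAP5SA replicate 2, and Hspa1b and Hspb1 when either YAP5SA library was left out. Of this list 7 fell and 1 rose without control replicate 1, and 6 fell and 6 rose without control replicate 2. Of the other added lists, muscle-restricted metabolic genes were lower (3 of 13 fell, median -0.80, camera adjusted p = 4.45e-07; adjusted p = 0.176 with an estimated correlation; 12 and 11 fell without control replicates 1 and 2, with 0 and 1 that rose, and 0 passed when either YAP5SA library was left out), and glucocorticoid-responsive genes were not called between the groups (1 of 16 rose, median -0.37, camera adjusted p = 0.673), except without control replicate 2 (median -0.61, camera adjusted p = 0.000222; the median was 0.14 without control replicate 1). Esr1, the estrogen receptor gene whose ligand-binding part is used in tamoxifen-inducible Cre proteins, was at 57.2 and 737 CPM in the control libraries and at 77.4 and 113 CPM in the YAP5SA libraries.

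The rise of macrophage, interferon and cell cycle genes was weighed against changes in the mix of nuclei. A lower share of cardiomyocyte nuclei, with the other cell types in unchanged proportions, would raise the markers of each of these alike. The endothelial median lay below 0 and below the macrophage median (-0.79, difference -2.27, permutation of members, two-sided p = 9e-05), which argues against that case. The p-value treats members as independent, and the difference was -2.37 to -2.09 when 1 library was left out. A lower share together with a changed mix of the other cells cannot be excluded by this comparison. Muscle genes were lower too: 23 of 24 sarcomere genes and 13 of 13 muscle-restricted metabolic genes had a negative fold change. A rise of macrophage nuclei alone may carry the whole cell cycle rise. With an unchanged share of dividing macrophages, this needs a G2/M median at or below that of the macrophage list. That share was not measured, so a higher G2/M median could not exclude macrophages. The G2/M minus macrophage difference was -0.264 (permutation p = 0.014, which treats members as independent). It depended on the control libraries, at -0.598 without control replicate 1 and 0.0465 without control replicate 2, so this explanation stays open. The most abundant macrophage gene tested, Lyz2, measured 257 and 212 CPM in control and 410 and 519 CPM in YAP5SA (adjusted p = 0.0758), and Mrc1 182 and 95.3 against 259 and 308 CPM, in nuclei selected by PCM1, a step meant to remove such cells. An effect of YAP5SA on cycling of the cardiomyocytes themselves stays open and was not tested, since RNA pooled over nuclei does not name the dividing cell.

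Transcripts of the skeletal myosin genes Myh1, Myh2 and Myh8 appeared in both YAP5SA libraries, Myh8 at 0.355 ± 0.246 CPM in control and 17.0 ± 4.36 CPM in YAP5SA (SD, n = 2; adjusted p = 0.0187, lost without YAP5SA replicate 2), while in the same cluster Myh4 and Myh13 stayed at 0 to 3 counts in each library and Myh3, too low to be tested, had 35 and 2 counts in control and 0 and 2 in YAP5SA (ratio 0.0359, 95% counting interval 0.00419 to 0.139). Skeletal muscle tissue in the samples would bring its other abundant transcripts, but 13 of 14 other skeletal muscle genes had a negative fold change (median -1.97). The exact sign test gave a two-sided p of 0.0018, and camera an adjusted p of 5.15e-17 (0.151 with an estimated correlation). The exception was Cacna1s, a calcium channel gene that rose. The sign test treats genes as independent, and Acta1, Tnnt3 and Myot had already been seen among the largest decreases. Acta1 and Ckm stood at 670 and 155 CPM in control, so a fall of their own could hide a small addition from skeletal muscle. Tnnt3 was left at 0.392 CPM in YAP5SA. Reads of cardiac myosin genes assigned to the skeletal myosin genes would follow Myh6 and Myh7. The summed CPM of Myh6 and Myh7 was lower in YAP5SA, at 2664 and 2930 against 5067 and 9003 (log2 ratio -1.33). Antisense transcripts overlap Myh1 and Myh2, and without a stated strand setting their reads remain possible sources that were not tested. For Myh8, no exon of another annotated gene overlapped its exons, and overlap with its introns was not checked. Transcription of these genes under YAP5SA was not tested by other means and stays a hypothesis found in these data.

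The control libraries differed from each other across many lists, with higher circadian and ATF4 genes in replicate 1 and higher calcium handling and sarcomere genes in replicate 2. A lower share of cardiomyocyte nuclei in replicate 1 would lower muscle-restricted metabolic genes about as much as the sarcomere genes (-0.86). Their median difference was 0.132, with 8 of 13 above 0 (exact sign test, two-sided p = 0.58). In the exact sign test added after that, 11 of 13 were above the sarcomere median (exact sign test, two-sided p = 0.022). The predicted fall of the metabolic genes was therefore not seen. Markers of 6 other cell types lay 0.19 to 0.68 higher in replicate 1, which goes with a lower share of cardiomyocyte nuclei, and erythroid genes lay lower (-0.86). Since these values point both ways, a lower share of cardiomyocyte nuclei in replicate 1 stays open. Glucocorticoid exposure may contribute: 16 responsive genes had a median difference of 0.668, at percentile 100 of 10000 random lists matched on expression. The ribosomal protein, mitochondrially encoded, NRF2, ATF4 and circadian lists also lay at percentile 100, so this test does not single out glucocorticoids. Less nascent RNA in replicate 1 may contribute too. The difference between the control libraries fell with gene length over 13741 protein coding genes (Spearman rho -0.18, across genes, which are not independent). The YAP5SA pair also differed by length (rho 0.13, against -0.032 for the fold change), and the design names no group that separates these 2 libraries. Between the control libraries, nuclear-retained lncRNAs lay lower in replicate 1 (median difference -1.1, percentile 0.12 of the random lists). Genes annotated as sense intronic took 0.0886% of the counts of control replicate 1 and 0.1775% of those of control replicate 2. Mitochondrially encoded and ribosomal protein genes lay higher in replicate 1 (0.812 and 0.43). A common cause of these differences was not tested.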
